A study of Anoxybacillus ayderensis with 6 samples.

How the data were processed

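RNA of the thermophilic bacterium Anoxybacillus sp. SK 3-4 was sequenced in 6 samples, 3 from medium with 0 mg/L aluminum and 3 from medium with 600 mg/L aluminum. Per the labels' protocols, an inoculum grown for 18 h in 25 mL of broth was moved into flasks with and without aluminum and kept for 3 h at 55 °C and 200 rpm. RNA was extracted with a bacterial column kit and cDNA was made with ScriptSeq Complete Kit (Bacteria), per the labels' protocols. The labels name one flask per aluminum level and do not say whether the 3 samples of a group came from separate cultures. The p-values given here therefore measure only the spread between these samples, which may be technical.

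The deposited values are whole-number read counts per gene, with no normalization, for 2846 gene rows per sample on 141 scaffolds. Each row carries a locus tag, a scaffold, a start, an end, a strand and a product description. The aligner, the counting program, the genome build and whether counting used strand are not given in the sources used here. Without a stated counting rule, reads from near-identical copies and from overlapping or antisense genes could not be told apart. Total counts ran from 2899047 to 4111761 per sample. Transfer and ribosomal RNA rows took 0.0445% to 0.0620% of them. Groups were taken from the treatment label and replicate numbers from the sample titles (1, 2 and 3 without aluminum, and 2, 3 and 5 with it).

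Counts were analysed in R 4.3.3. The main test was the quasi-likelihood F-test of edgeR 4.0.16 after its expression filter and TMM scaling, with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and 2571 genes passed the filter. Levels are given as CPM of the TMM-scaled library, as mean ± SD over 3 samples. Log2 fold changes are 600 against 0 mg/L, with the standard error (SE) derived from the fitted change and its F statistic. On simulated counts for this comparison, drawn from the real means, library sizes and dispersions with 200 genes changed and 2571 genes tested, the test called 82.0% of genes changed 2-fold, 99.0% of genes changed 4-fold and 0.7% of unchanged genes. A simulated list with raised members was called and 0 of 20 random lists were. Simulated genes varied independently of each other, so this does not measure how often lists of correlated genes are called wrongly. The real samples of a group also differed in many genes together, so the rates for single genes may not hold for them. The changed genes were drawn only from those with a mean of at least 20 counts.

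A set of 25 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. List members were matched by words in the product description, since the rows hold no gene symbols, so a name can match a list without belonging to it. Of the genes, 1000 fell in at least 1 list and 25 in more than 1. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. The genes named were the 12 largest rises and the 12 largest falls among called genes with separated groups, a mean level above the median and a product of known function, up to 4 members of each list with the smallest p-values, and the 5 rows with the highest mean level. Genes outside that rule are identified where they appear.

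The alternatives chosen in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile scaling, no filter, a filter at a mean of 50 counts, structural RNA and the 5 most abundant rows left out, a 2-fold minimum, each sample left out in turn, the replicate number as a block, camera with an estimated correlation, and fry. An alternative pseudocount did not apply to counts. Added later were hand-checked lists, with wrongly matched names removed before any test was run, and a covariate for the leading difference between samples of one group, chosen after the results had been seen. No pair of samples agreed within sampling noise. The most alike were untreated replicates 1 and 3, with a chi-square per degree of freedom of 3.42.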

Results

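Gene expression was compared between cells of Anoxybacillus sp. SK 3-4, a heat-loving bacterium whose source the labels give as a hot spring, kept for 3 h with 600 mg/L aluminum and cells kept without it. Each group held 3 samples. Totals were 3234897, 2899047 and 3161654 counts for untreated replicates 1, 2 and 3, and 3206354, 3561673 and 4111761 counts for aluminum replicates 2, 3 and 5. The question, as the series title states it, was how the transcriptome responds to aluminum.

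The first principal component held 75.6% of the variance and separated the groups, with untreated samples between -20.5 and -15.4 and aluminum samples at 3.10, 19.2 and 29.3. The aluminum samples were more spread out than the untreated samples. Aluminum replicate 2 lay nearest to the untreated group on this component and apart from the other samples on the second component, at -17.8.

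**Figure D1:**
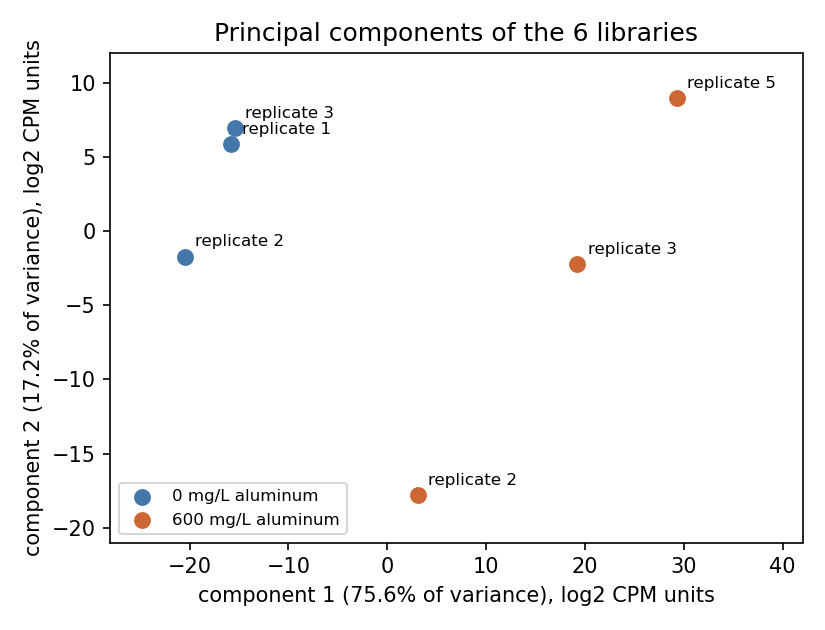
Principal components of log2 CPM for the 6 samples, with each point a sample and colour giving the aluminum level. The untreated samples sit between -20.5 and -15.4 on component 1 and the aluminum samples between 3.10 and 29.3.

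With aluminum, 286 genes were higher and 188 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was seen in 88 of the higher and 73 of the lower genes. The largest rise was in a gene annotated as phage shock protein A or LiaH, a family of membrane-associated proteins known from the cell envelope stress response. Genes for uptake of ribose or xylose and of trehalose or maltose, and genes for sulfate assimilation, also rose. The largest falls were in phosphoenolpyruvate carboxykinase and a glyceraldehyde-3-phosphate dehydrogenase. In all 474 called genes the 3 samples of one group lay above the 3 of the other. That was so in 41.1% of all tested genes, where chance gives 10%. The counts depended on the samples used. Leaving out untreated replicate 1, 2 or 3 gave 117, 141 or 128 higher and 67, 91 or 71 lower genes, leaving out aluminum replicate 3 gave 122 and 65, and leaving out aluminum replicate 2 gave 674 and 645. A set of 169 genes was called in the same direction in all 6 such fits.

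The LiaH gene C289_RS13540 (scaffold 96, 1569 to 2192, minus strand) went from 20.2 ± 1.88 CPM without aluminum to 3071 ± 732 CPM with it (SD, n = 3). Its log2 fold change was 7.24 (SE 0.24, edgeR adjusted p = 5.1e-06), a 152-fold rise. A second gene with the same annotation, C289_RS05270 (scaffold 16, 29218 to 29850, minus strand), went from 34.2 ± 5.32 to 379 ± 71.1 CPM (SD, n = 3), a log2 fold change of 3.47. Reads shared between these genes could not be excluded, since the counting rule is not given. Both matched the prophage list by the word phage. That list had 8 members higher and 13 lower of 79, and 8 and 14 adjusted over the list alone, and was not called (camera adjusted p = 0.746). Without the wrongly matched names its adjusted p was 0.472.

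The ribose transporter ATP-binding gene C289_RS02890 (scaffold 8, 85737 to 87245) rose 53.9-fold, from 46.3 ± 2.62 to 2495 ± 504 CPM (SD, n = 3), and the neighbouring permease C289_RS02885 rose 47.5-fold. On scaffold 41, the binding protein gene C289_RS09335 (11718 to 13025) rose 14.6-fold to 9472 ± 2158 CPM (SD, n = 3). The permease genes C289_RS09330 and C289_RS09325 rose 11.6-fold and 10.8-fold, and the regulator gene C289_RS09340 rose 8.81-fold. On scaffold 76, trehalose-6-phosphate hydrolase (C289_RS12985), which cleaves imported trehalose phosphate, rose 7.69-fold and the trehalose phosphotransferase gene C289_RS12980 rose 7.59-fold. In the sugar and peptide uptake list, 10 of 42 members were higher and 2 lower over all genes, and 10 and 4 when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.057, and adjusted p = 0.351 with an estimated correlation). It was called without untreated replicate 1 (adjusted p = 0.039), without aluminum replicate 2 (0.048) and without aluminum replicate 3 (0.035).

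The sulfur assimilation, cysteine and methionine list had 19 of 36 members higher and 0 lower, and 22 higher and 1 lower adjusted over the list alone. Its median log2 fold change was 0.61 (camera adjusted p = 3.3e-08). With an estimated correlation the adjusted p was 0.317. Adenylylsulfate kinase (C289_RS01945, scaffold 4, 16294 to 16881), which activates sulfate, went from 43.6 ± 4.72 to 345 ± 55.8 CPM (SD, n = 3). Sulfate adenylyltransferase (C289_RS01950) rose 6.54-fold, the sulfate permease gene C289_RS01955 rose 4.61-fold and methylthioribose-1-phosphate isomerase of methionine salvage (C289_RS03685) rose 7.59-fold. Uroporphyrin-III C-methyltransferase (C289_RS01940), which acts in siroheme synthesis, lay in the same run and rose 7.33-fold. The list's median difference between aluminum replicates 5 and 2 was 0.18 on the log2 scale.

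**Figure D2:**
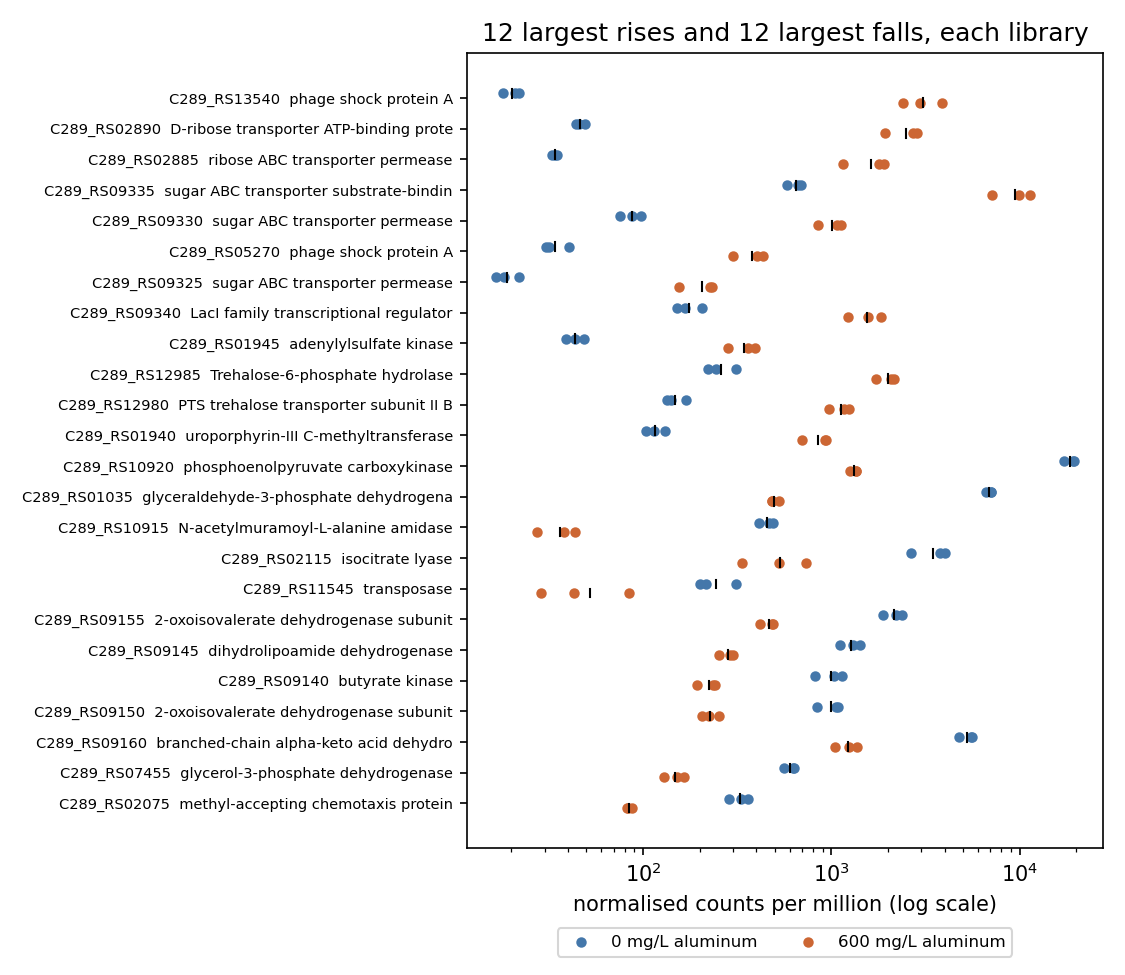
Normalised read counts in CPM in each sample, on a log axis, for the 12 largest rises and the 12 largest falls named by the fixed rule, with points for samples and short lines for group means. The means of C289_RS13540 lie at 20.2 and 3071, and those of C289_RS10920 at 18563 and 1317.

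Among genes that fell, phosphoenolpyruvate carboxykinase (C289_RS10920, scaffold 47, 44911 to 46497, minus strand), which commits carbon to gluconeogenesis, went from 18563 ± 1174 to 1317 ± 50.1 CPM (SD, n = 3), a log2 fold change of -3.82 (SE 0.12, edgeR adjusted p = 5.1e-06). The glyceraldehyde-3-phosphate dehydrogenase gene C289_RS01035 (scaffold 3, 39754 to 40782) went from 6892 ± 257 to 498 ± 22.7 CPM (SD, n = 3), 13.8-fold lower. The amidase gene C289_RS10915, next to the carboxykinase, was 12.6-fold lower. Isocitrate lyase of the glyoxylate bypass (C289_RS02115) was 6.54-fold lower, at 531 ± 199 CPM with aluminum (SD, n = 3). Genes C289_RS09140 to C289_RS09160 on scaffold 39, annotated as butyrate kinase and subunits of the branched-chain keto acid dehydrogenase, which breaks down branched-chain amino acids, were 4.33-fold to 4.64-fold lower. Aerobic glycerol-3-phosphate dehydrogenase (C289_RS07455) was 4.09-fold lower, a chemotaxis receptor gene (C289_RS02075) 3.86-fold lower and a transposase gene (C289_RS11545) 4.68-fold lower. The transposase call was the only one of these 12 falls lost when a sample was left out.

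The glycolysis and gluconeogenesis list had 8 of 16 members higher and 3 lower, with the same counts adjusted over the list alone. Its median log2 fold change was 0.68 (camera adjusted p = 0.023). With an estimated correlation the adjusted p was 0.351, although the estimate for this list was 0.01, the same as the preset. Triosephosphate isomerase (C289_RS00470) rose 3.48-fold and phosphoglyceromutase (C289_RS00465) rose 2.92-fold, while the carboxykinase and C289_RS01035 fell. The citrate cycle and pyruvate dehydrogenase list had 8 of 22 members higher and 4 lower, with the same counts adjusted over the list alone, and was not called (camera adjusted p = 0.377). Its test and mean pointed upward and its median log2 fold change was -0.01. The gene C289_RS04720 rose 4.76-fold, and a malic enzyme gene (C289_RS03875) rose 3.90-fold. C289_RS04720 is named both for the branched-chain keto acid dehydrogenase and for the pyruvate dehydrogenase complex. So is C289_RS09160, which was 4.33-fold lower, and the names do not tell which complex each belongs to. Outside the naming rule, C289_RS04715, C289_RS04725 and C289_RS04730 of the list also rose, with log2 fold changes of 1.97, 2.08 and 2.25.

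Translation factors and aminoacyl-tRNA synthetases had 11 of 34 members higher and 0 lower, and 14 and 0 adjusted over the list alone (camera adjusted p = 0.001, median log2 fold change 0.32). With an estimated correlation the adjusted p was 0.417. Threonyl-tRNA synthetase (C289_RS01070) rose 2.31-fold and elongation factor Tu (C289_RS09615) rose from 12037 ± 189 to 21838 ± 1716 CPM (SD, n = 3). The list's median difference between aluminum replicates 5 and 2 was 0.24, close to its median change. Branched-chain and aromatic amino acid synthesis had 11 of 34 members higher and 3 lower, and 13 and 6 adjusted over the list alone (camera adjusted p = 0.037, median 0.19). That call was lost with an estimated correlation (adjusted p = 0.626), with DESeq2 size factors (adjusted p = 0.051) and without aluminum replicate 5 (adjusted p = 0.081). It was also lost with wrongly matched names removed (adjusted p = 0.083) and with the replicate number as a block (adjusted p = 0.112). The shikimate pathway gene C289_RS07625 rose 2.90-fold and ketol-acid reductoisomerase (C289_RS01315) rose 2.09-fold. The 3 lower members, which lie outside the naming rule, were C289_RS07655, C289_RS07660 and C289_RS07665. Their locus numbers follow each other, and their log2 fold changes were -1.05, -0.84 and -0.92, so the list did not move as a whole. The list's median difference between aluminum replicates 5 and 2 was 0.29, larger than its median change.

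**Figure D3:**
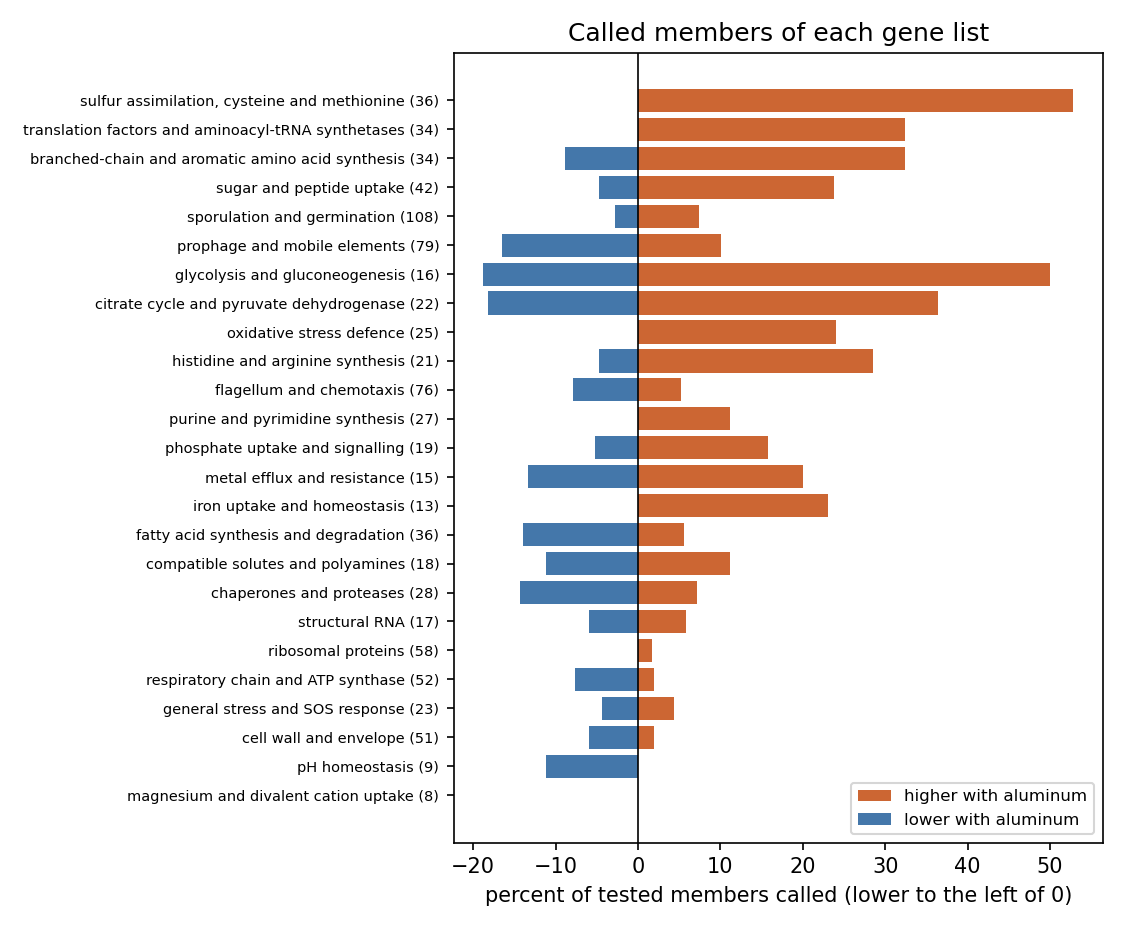
Percent of tested members of each of the 25 gene lists called higher (right of 0) or lower (left of 0) with aluminum, with the number tested in brackets. The sulfur list had 19 of 36 members higher and 0 lower.

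None of the stress and metal lists was called by camera. Oxidative stress defence had 6 of 25 members higher and 0 lower (camera adjusted p = 0.078). Manganese superoxide dismutase (C289_RS08720) rose 2.38-fold and thiol peroxidase (C289_RS00860) rose 2.15-fold. Iron uptake had 3 of 13 members higher and 0 lower (0.195), with a ferrichrome transporter ATP-binding gene (C289_RS07410) 3.19-fold higher. Metal efflux and resistance had 3 of 15 members higher and 2 lower (0.719). Its test and mean pointed upward and its median log2 fold change was -0.10. Magnesium and divalent cation uptake had 0 of 8 members called (0.378). Phosphate uptake and signalling had 3 of 19 higher and 1 lower (0.753), with a downward test and a median of -0.20, and with a phosphate-binding protein gene (C289_RS05250) 3.01-fold higher. Chaperones and proteases had 2 of 28 higher and 4 lower (0.470), and DnaK (C289_RS08335) was 1.58-fold lower. The DnaK call held in only 2 of the 6 fits with a sample left out. General stress and SOS response had 1 of 23 higher and 1 lower (0.746), and pH homeostasis had 0 of 9 higher and 1 lower (0.195). Adjusted over the list alone, the members higher and lower were 7 and 0 for oxidative stress, 4 and 0 for iron, 4 and 2 for metal efflux, 0 and 0 for magnesium, 3 and 1 for phosphate, 2 and 4 for chaperones, 1 and 0 for general stress, and 0 and 0 for pH homeostasis.

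For the remaining lists, none of which was called by camera, the numbers in brackets are camera adjusted p-values. Histidine and arginine synthesis had 6 of 21 members higher and 1 lower (0.337), with an upward test and mean and a median of -0.10. Purine and pyrimidine synthesis had 3 of 27 higher and 0 lower (0.377), with an upward test, a median of 0.20 and a mean of -0.18. Ribosomal proteins had 1 of 58 higher and 0 lower (0.376), with a downward test, a median log2 fold change of -0.12 and a median difference of -0.59 between aluminum replicates 5 and 2. The respiratory chain had 1 of 52 higher and 4 lower (0.376), and fatty acid synthesis and degradation had 2 of 36 higher and 5 lower (0.167), with median differences between those replicates of 0.37 and 0.61. The fatty acid list was called as lower without untreated replicate 2 (0.024) or aluminum replicate 5 (0.006), and with the replicate number as a block (0.007). Flagellum and chemotaxis had 4 of 76 higher and 6 lower (0.119), cell wall and envelope 1 of 51 higher and 3 lower (0.185), and sporulation and germination 8 of 108 higher and 3 lower (0.195). The sporulation test pointed downward, with a median log2 fold change of -0.22 and a mean of -0.29. Without aluminum replicate 2, the ribosomal protein and sporulation lists were both called as lower (0.048 each). Compatible solutes and polyamines had 2 of 18 higher and 2 lower (0.746), and structural RNA, most of whose tested members were RNA-modifying enzymes matched by name, had 1 of 17 higher and 1 lower (0.753). Adjusted over the list alone, the members higher and lower were 6 and 2 for histidine and arginine, 3 and 0 for purines and pyrimidines, 0 and 0 for ribosomal proteins, 0 and 0 for the respiratory chain, 3 and 7 for fatty acids, 4 and 5 for flagellum and chemotaxis, 1 and 3 for cell wall, 3 and 1 for sporulation, 2 and 2 for compatible solutes, and 1 and 1 for structural RNA.

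The 5 most abundant rows included a gene of unknown product (C289_RS05825, scaffold 22), which rose 1.76-fold to 79290 ± 12311 CPM (SD, n = 3). A subtilisin-like protease gene (C289_RS05845) rose 1.53-fold and an aldehyde-alcohol dehydrogenase gene (C289_RS04275) rose 1.92-fold. The calls of C289_RS05825 and C289_RS05845 each held in only 2 of the 6 fits with a sample left out, and that of C289_RS04275 in all 6. The RNA helicase gene C289_RS12375 did not differ beyond the spread between samples (log2 fold change 0.25, SE 0.14, edgeR adjusted p = 0.242).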

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

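Of the settings here, the within-group covariate and the hand-checked lists were not planned. With all 6 samples, other tests, scalings and filters gave 275 to 331 higher and 178 to 232 lower genes. A 2-fold minimum left 88 and 73 by construction. Leaving out a sample gave 117 to 674 higher genes, 65 to 645 lower genes and 4 to 7 called lists, with the extremes of the gene counts reached without untreated replicate 1, aluminum replicate 3 or aluminum replicate 2. The within-group covariate gave 629 higher and 884 lower genes. It was derived from the residuals it removes, which by itself raises counts. Replicate numbers 2 and 3 occur in both groups, and the deviations of same-numbered samples correlated at 0.64 and 0.21 across genes. With only 2 shared numbers and no stated pairing, whether the number marks a shared batch could not be told. With the replicate number as a block, 324 genes were higher, 295 lower and 4 lists called, without the branched-chain list (adjusted p = 0.112) and with the fatty acid list (0.007). For lists, 0 were called with an estimated correlation and 11 with fry, which does not compare a list with other genes. Beside the lists that camera called, fry called oxidative stress (fry adjusted p = 0.006), histidine and arginine (0.015), purines and pyrimidines (0.024) and sugar uptake (0.001) as higher. It called pH homeostasis (0.012), magnesium (0.024) and flagellum and chemotaxis (0.029) as lower. The estimated correlation of the glycolysis list was 0.01, as preset, so its lost call does not come from a larger correlation. The estimates were 0.05, 0.07 and 0.10 for the sulfur, translation and branched-chain lists. Otherwise the causes of these differences were not tested. Directions that turned belonged to uncalled results. Adjusted p-values were 0.873 for the citrate cycle list and 0.873 for the phosphate list under the block. Leaving out a sample gave 0.436 to 0.959 for compatible solutes and 0.675 to 0.947 for general stress, both turned without aluminum replicate 5. It gave 0.578 to 0.985 for phosphate, turned without untreated replicate 2 or aluminum replicate 5 (0.863), and 0.497 to 0.937 for prophage, turned without aluminum replicate 2. Phosphate also turned with hand-checked lists (0.828) and prophage with the covariate (0.952). The log2 fold change of C289_RS02975 ran from -0.13 to 0.01, the latter without aluminum replicate 2.

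Only 10 splits of the 6 samples into 3 and 3 exist, too few for a share under 0.05. The real split gave 286 higher and 188 lower genes, and the highest of the other splits gave 0, so 1 split reached each real count. For list tests the real split called 4 lists, another called 8, and 5 of the 10 splits called as many.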

Other observations

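Tests chosen only after their results had been seen were those of untreated RNA, of an unequal response, of the within-group axis in carbon genes and of sugar repression, and the intervals required of the depth and read-overlap tests were also added after their values had been seen. Other genes beside those already described changed, and those named in the next sentences lie outside the fixed rule and were chosen after their values were seen. Next to the LiaH gene C289_RS13540, a hypothetical gene, C289_RS13545, rose from 3.89 ± 0.736 to 340 ± 114 CPM (SD, n = 3). Next to C289_RS05270, a hypothetical gene, C289_RS05275, rose 10.8-fold, and the regulator gene C289_RS05285 rose 3.71-fold. In contrast, the 2 genes whose products are named for aluminum resistance were not called. C289_RS05560 had a log2 fold change of 0.18 (SE 0.12, edgeR adjusted p = 0.319) and C289_RS11390 had 0.22 (SE 0.41, edgeR adjusted p = 0.716). For these genes a change was not shown, and its absence was not shown either.

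Samples of one group differed along an axis that both groups shared, which held 78.6% of the within-group variance, with scores of 2.54, -6.11 and 3.57 for untreated replicates 1, 2 and 3 and -19.9, 2.42 and 17.5 for aluminum replicates 2, 3 and 5. Genes called at least 2-fold without aluminum replicate 2 gave its position between untreated (0) and the other aluminum samples (1). The median position was 0.68 for 113 rises and 0.27 for 253 falls. Both medians met the rule first written for untreated RNA, which asked only for positions well short of 1. Choosing genes without that sample can itself lower its position. The gap between the medians was 0.41, where one share of untreated RNA in aluminum replicate 2 would place both alike. The rises would need a share of 0.32, and 19 genes with at least 100 CPM without aluminum lay in that sample below 0.32 of their untreated level, which argues against untreated RNA at that share. Within-group differences were taken as aluminum replicate 5 minus 2, and untreated replicate 2 minus the mean of replicates 1 and 3. The minus sign of their correlation comes from that order of subtraction. Thinning each sample to the smallest total removed up to 29.5% of a sample's counts. It left the correlation across genes at -0.61 (95% bootstrap interval over genes, taken as independent, -0.64 to -0.58), which argues against the number of counts itself. Totals did rise with the score across the aluminum samples, and untreated replicate 2 had the lowest of both in its group. Anything else that goes with the totals was not tested. An unequal response to aluminum cannot account for the spread of the untreated samples, which received none. For the aluminum samples an unequal response stays open, since the unthinned correlation of -0.62 restates the pattern. A batch marked by the replicate number stays open as well. Replicate 2 had the lowest score in both groups, while replicate 3 was highest only in the untreated group. Base composition and culture handling were not tested.

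In the 3 carbon lists (glycolysis, citrate cycle and sugar uptake), 26 of the 35 called members rose and 9 fell. Camera adjusted p-values were 0.023, 0.377 and 0.057 for the lists and 0.351, 0.877 and 0.351 with an estimated correlation. With wrongly matched names removed they were 0.026, 0.785 and 0.083. The counts are of members matched by name. Among the rises, C289_RS01320 and C289_RS01325 are also in the branched-chain synthesis list and C289_RS07195 in the sulfur list. Among the falls, C289_RS09145 and C289_RS09160 lie in the branched-chain keto acid dehydrogenase run. With the most abundant rows left out before scaling, 100% of the 35 stayed called in their direction. That outcome adds little, since leaving them out moved the median log2 fold change of all tested genes only from -0.08 to -0.02. The 20 largest rows of a sample held at most 29.7% of its counts, which argues against a few genes taking most of the counts. The within-group axis had the sign of the change in 80.0% of the 35, against 76.6% of all called genes, and in 33.3% of the 9 falls (95% exact binomial interval 7.49% to 70.1%, taking genes as independent), which argues against it for the falls. It stays open for the 26 rises, since its slope over genes outside these lists predicted a median log2 change of 0.16 where 1.70 was observed, but it fell short in the same way for 99.6% of the 260 called rises outside these lists. Repression by plentiful sugar stays open, since the 10 rises among sugar and peptide uptake genes are part of the pattern itself and no carbon source was measured.

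Neighbouring genes changed together. Log2 fold changes of adjacent genes correlated at 0.68 over 1828 pairs on the same strand and 0.17 over 478 pairs on opposite strands. The difference of 0.51 (95% bootstrap interval 0.39 to 0.62) is in line with shared transcripts. Reads reaching from one gene into the next stay open. For 70 same-strand pairs over 300 bases apart the difference was 0.10 (0.099 before rounding). That met the bound of under 0.1 set in advance for such reads as the cause. The interval of this difference, -0.12 to 0.29, required only afterwards, was too wide to decide. Even a low difference could not single out such reads, since genes that far apart may also share fewer transcripts.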
